A study of Mus musculus with 27 samples.

How the data were processed

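RNA was measured in naive mouse CD4 T cells from spleen and lymph node (1 library) and in cells activated with plate-bound anti-CD3 at 5 µg/ml and anti-CD28 at 2 µg/ml (15 libraries). The activated cells received no added cytokine (Th0), TSLP at 40 ng/ml, or IL-4 at 20 ng/ml (Th2), and were taken at 2, 6, 24, 48 and 72 h. Chromatin immunoprecipitation gave peak lists for H3K4Me3, H3K27Ac and H3K36Me3 at 72 h in samples labelled Th0, TSLP and Th2. The Th0 chromatin labels carry the text aIL4/4R and the Th0 RNA labels do not, so whether these cultures matched is not given in the sources used here. A further pair of lists gave STAT5 binding in cells that were activated for 3 days, rested for 3 days and then kept in medium or given TSLP for 25 min, and whose treatment text also names IFNg with no stated role. Each of the 27 samples was the only library of its group.

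The submitters' processing notes name STAR 2.4.2a, Bowtie 1.1.1 and MACS2 2.1.0.20140616 without saying which step each served, and the sample descriptions name BioWardrobe. The read counter, its annotation version, the control library and the caller settings are not given in the sources used here. Each deposited RNA file holds raw counts of reads per RefSeq transcript entry and RPKM values per the file headers. RPKM relates the reads to transcript length and library total, as scaled by the authors. Counts of entries with the same gene symbol were added, which turned 26049 entries into 23335 symbols, 2050 of them with more than 1 entry. Each deposited peak file gives fold enrichment, a ratio over the caller's background at the summit, per the file headers. The same deposited files give the fragment pileup (signal) at the summit, with no statement whether it was scaled, and the −log10 of p and q. Peak annotation to a gene and a region (promoter, upstream, exon, intron, intergenic) is that of the authors. Coordinates were counted from 1, and the gene starts in the files equal those of the GRCm38 annotation.

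Gene counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with at least 1 CPM (counts scaled to a common library total) in at least 2 of the 15 activated libraries were kept, which left 11797 genes and at least 99.9% of the reads of each library. TMM factors scaled the libraries. A quasi-likelihood fit with robust dispersion had time as a block and the arm as the effect, with 8 residual degrees of freedom. All 3 arms were in the same fit. Because no group had a second library, its p-values measure how an arm's difference varied among the 5 times, and a gene that responded at 1 time only has a large error. Standard errors (SE) are those of the fitted log2 fold change. Change of the effect with time was tested with arm by log2(hours) terms, with 6 residual degrees of freedom, and is given as log2 units per doubling of time. Values of p were adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05.

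Library totals ranged from 21830854 to 66055994 reads. Ratios between a pair of libraries at 1 time used CPM scaled by TMM with 1 CPM added. Genes with at least 5 CPM in either library were counted when they stood at least 2-fold apart, with no p-value. Intervals on ratios of reads are 95% intervals from the binomial distribution and cover counting error only, as do the Wilson intervals on shares of peaks. Gene lists were compared between the naive and Th0 libraries by the percentile of the list's median among 10000 random lists matched on mean expression.

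Lists of genes, 25 in all, were written from general knowledge before the data were examined, as were the comparisons, tests, filters and most alternatives. The 18 lists of T cell programmes were STAT5 and cytokine feedback, response to IL-4, Th2 cytokines, Th2 effector genes, Th1, Th17, follicular helper, regulatory T cell, cytokine receptors, immediate early genes, quiescence, cell cycle, glycolysis, cholesterol synthesis, ATF4 and amino acid genes, interferon-stimulated genes, survival and apoptosis, and checkpoint receptors. A further list held CD4 T cell identity genes, and 6 lists held markers of B, CD8 T, NK, myeloid and dendritic, basophil and mast, and erythroid cells. The 24 lists with at least 2 measured members were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, beside camera with an estimated correlation and fry.

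Genes were named by a rule. In each comparison of arms it took the 8 largest rises and the 8 largest falls past adjusted p 0.05 with a mean of at least 5 CPM and the same sign at all 5 times. It added the called members of the feedback, Th2 cytokine, Th2 effector and IL-4 response lists, and 13 genes whatever their result: Il4, Il13, Il5, Gata3, Il4ra, Il1rl1, Cish, Bcl6, Tbx21, Ifng, Foxp3, Crlf2 and Il7r. The 5 largest rising and falling changes with time were named, as were the 5 largest rises and falls from naive to Th0 cells at 2 and 72 h with at least 20 CPM in the higher library. Other lists gave up to 4 members with large fitted changes. Not every gene the rule picks is given in the text. Other genes were picked after their values were seen: other TSLP calls, and peaks ranked after removing those that overlap a medium peak.

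Peak lists were compared in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Lines of the files that share a start and end were merged into 1 peak, and peaks on the mitochondrial chromosome were set aside. A peak counted as overlapped when a peak of the other list covered at least 1 bp of it. Strong peaks are those with a −log10 q of at least 10. Genes annotated to a peak of 1 arm that no peak of the other arm overlapped, and with no peak of their own in the other arm, were tested as sets with camera, 13 sets with the STAT5-bound genes included.

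The relation of the TSLP and Th2 effects shares the Th0 libraries, so it was set beside 100 simulated draws in which neither cytokine changed a gene and beside fits in which the arms used different Th0 libraries. The fits were tested on simulated data with known changes placed in libraries of the same depth and spread. Of the genes given a change of 2-fold, 85.1% were called, and 76.1% of those given 1.5-fold. Each of these changes was the same at every time, so the shares do not apply to genes whose effect varied among the times. In that simulation 17 of 189 calls were false. A simulated slope of 0.4 was recovered in 157 of 200 genes.

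The alternatives were RLE size factors, no filter and a stricter filter, DESeq2 1.42.0, limma on log2(RPKM + 1) and log2(RPKM + 0.1), only the libraries of the compared arms, no time block, each time left out in turn, other floors and pseudocounts, stricter peaks and other overlap rules. Fits with the 24, 48 and 72 h libraries alone, and the STAT5 set without medium peaks, were added after seeing the data. A search for the STAT5 motif needs genome sequence and was not run.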

Results

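Naive mouse CD4 T cells were activated through CD3 and CD28 alone (Th0), with TSLP, or with IL-4 (Th2), and their RNA was followed over 3 days. TSLP is an epithelial cytokine that signals through STAT5, and IL-4 is the cytokine classically used to drive Th2 differentiation through STAT6. The 16 RNA libraries comprised 1 of naive cells and 1 of each arm at 2, 6, 24, 48 and 72 h. The 11 chromatin samples gave lists of H3K4Me3, H3K27Ac and H3K36Me3 peaks in each arm at 72 h, and of STAT5 peaks in rested cells kept in medium or given TSLP for 25 min. No group had a replicate. The labels of the Th0 chromatin samples carry the text aIL4/4R, which they do not explain and which the labels of the Th0 RNA libraries lack. Whether the Th0 cultures were the same for RNA and chromatin is not given in the sources used here. The treatment text of the STAT5 samples also names IFNg, with no stated role.

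The naive library held 24439823 reads. The Th0 libraries held 43824081, 59232421, 51109441, 33451701 and 21830854 reads at 2, 6, 24, 48 and 72 h. The TSLP libraries held 37444069, 23161173, 31930482, 41086476 and 22921276 reads, and the Th2 libraries 66055994, 27300167, 30830636, 29103071 and 22901250 reads. Time separated the activated libraries far more than the arm did. The leading 3 principal components carried 60.4, 18 and 8.12% of the variance, and time accounted for 99.9, 99.6 and 99.5% of each. The arm accounted for 14.5% of the 4th, which carried 4.11% of the variance.

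TSLP raised the Th2 cytokine genes Il13, Il5 and Il9 without added IL-4. Fitted over the 5 times in edgeR, Il13 was 2.89 log2 units higher with TSLP than in Th0 cells (SE 0.387, adjusted p 0.0171, higher at 5 of 5 times). Il5 was 3.67 units higher (SE 0.578, adjusted p 0.0468, 4 of 5 times), and Il9 was 3.75 units higher (SE 0.464, adjusted p 0.0131) at a mean of only 2.44 CPM. At 72 h Il13 stood at 22.1 CPM in Th0, 327 in TSLP and 81 in Th2 cells, and Il5 at 2.39, 98.2 and 15.1 CPM. The ratio of TSLP to Th0 reads at 72 h was 14.8 for Il13 (95% interval 13.5 to 16.2) and 41.1 for Il5 (31.6 to 54.6). The Il13 ratio was already 2.38 at 2 h (1.77 to 3.22).

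TSLP also raised Inhba, Lama5, Nek6 and Kcnk5 and lowered Marcksl1, Itm2a and Traf1. Inhba, which encodes an activin subunit, was 2.12 log2 units higher (SE 0.284, adjusted p 0.0157). The laminin gene Lama5 rose by 1.44, the kinase gene Nek6 by 1.41, the growth factor gene Fgf2 by 1.41, the potassium channel gene Kcnk5 by 1.17, the receptor gene Gpr83 by 0.70 and Tmem64 by 0.48, with adjusted p from 0.00858 for Kcnk5 to 0.0469 for Fgf2. Marcksl1 fell by 0.66 on the log2 scale (SE 0.0913, adjusted p 0.0131), Itm2a by 0.71 (SE 0.123, adjusted p 0.0469), Elk3 by 0.57, Zfp862 by 0.56, Traf1 by 0.54, Lrig1 by 0.49 and Evi2b by 0.45. The joint entry of Evi2a and Evi2b fell by 0.81, but its exons overlap Evi2b, so which gene its reads came from is uncertain. These 15 genes moved the same way at all 5 times. Other calls were Stra6 (2.23), Gpr146 (0.47), Errfi1 (0.45), Fndc3a (0.41) and Inpp4b (0.36), with adjusted p of 0.0469 or lower, and the scarcely expressed Htr1b and Pappa2, whose means were 0.321 and 0.539 CPM.

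In all, 26 of 11797 genes passed in TSLP against Th0 cells, 16 higher and 10 lower, and 1244 had an unadjusted p under 0.05. The count was 48 with 2 h left out, 4 without 6 h, 6 without 24 h, 0 without 48 h (775 at unadjusted p under 0.05) and 6 without 72 h. Of the 18 called genes named by rule, 17 kept their call without 2 h, 3 without 6 h, 3 without 24 h, 0 without 48 h and 4 without 72 h. Without 48 h the adjusted p was 0.137 for Il13, 0.25 for Il5, 0.253 for Il9, 0.137 for Inhba and 0.117 for Kcnk5. DESeq2 called 208 genes, 24 of them among the 26, and limma on log2(RPKM + 1) called 7. edgeR called 52 on only the libraries of these arms, 17 of them among the 26, and 0 without the time block (40 at unadjusted p under 0.05).

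Il4, Gata3, Cish and Bcl6 stood more than 2-fold apart between TSLP and Th0 cells at some times but did not pass over the 5 times. Il4 was 2.03 log2 units higher on average (SE 0.509, adjusted p 0.174), with 0.384 CPM in Th0, 9.53 in TSLP and 14.6 in Th2 cells at 72 h. The reads at 72 h gave Il4 ratios to Th0 of 24.8 for TSLP (12.9 to 55) and 38.1 for Th2 (19.8 to 84), resting on 9 Th0 reads. Gata3, the master transcription factor of Th2 cells, was 1.07 units higher (SE 0.234, adjusted p 0.108). Its TSLP to Th0 ratio went from 1.14 at 2 h (1.05 to 1.22) to 3.6 at 72 h (3.45 to 3.76), whereas the Th2 ratio was already 3.59 at 2 h (3.4 to 3.8). The STAT5 target Cish averaged 0.96 (SE 0.323, adjusted p 0.31), with ratios of 2.48 at 2 h and 4.65 at 6 h. Bcl6 averaged −1.54 (SE 0.477, adjusted p 0.264), with a ratio of 0.178 at 2 h (0.171 to 0.186) and 0.943 at 72 h. The log2 estimates were 0.37 for Il4ra (adjusted p 0.567), 0.45 for Il1rl1 (0.465), 0.49 for Tbx21 (0.548), 0.62 for Ifng (0.408), −0.10 for Foxp3 (0.962), −0.16 for the TSLP receptor gene Crlf2 (0.625) and 0.39 for its partner Il7r (0.737).

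**Figure D1:**
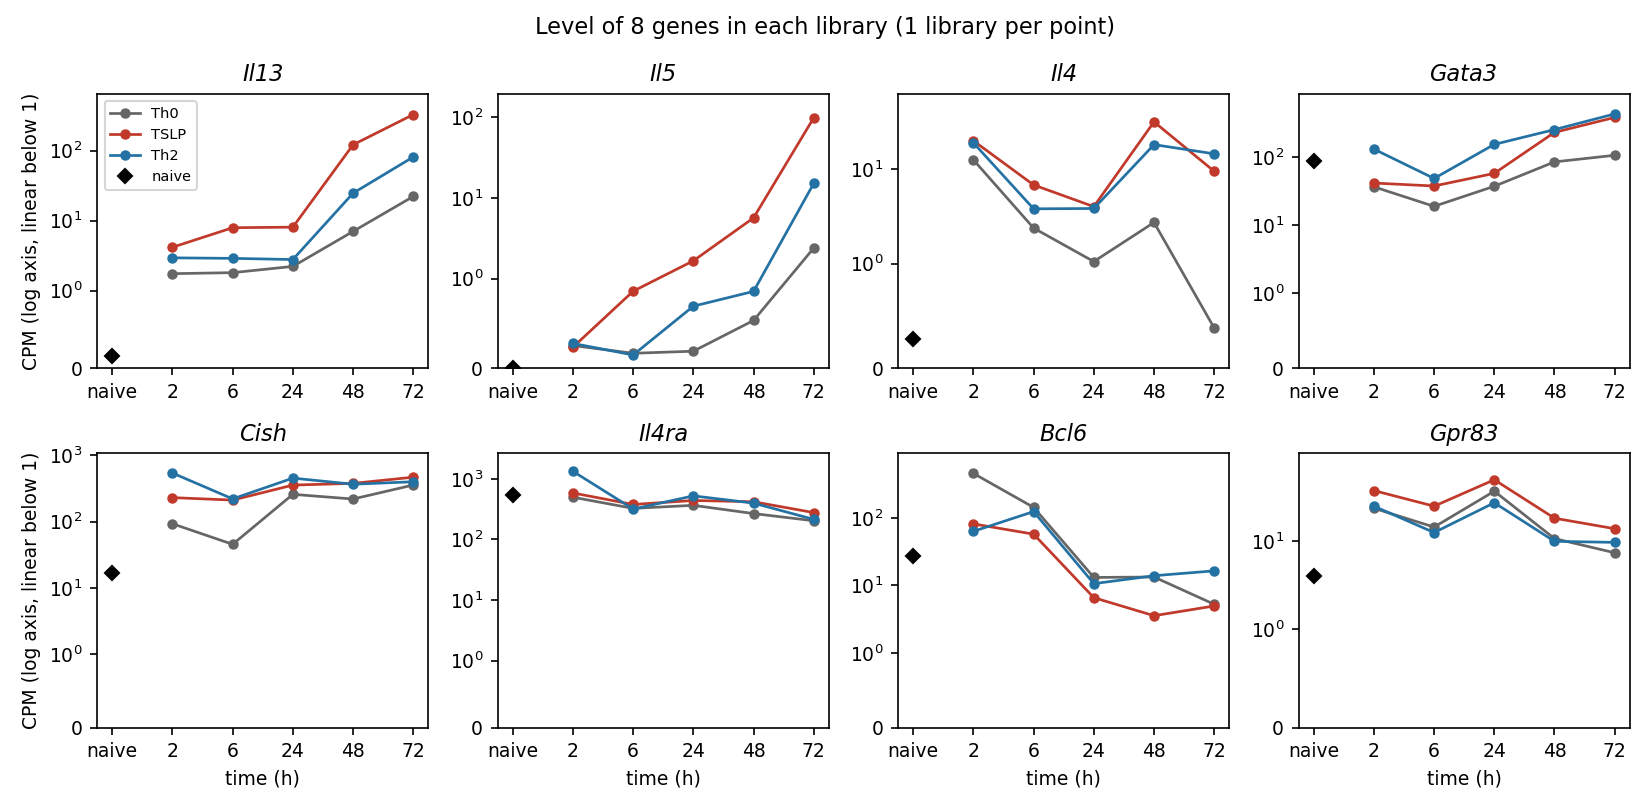
Levels of 8 genes in CPM on a log axis (linear below 1) against time, with 1 library per point, in naive (diamond), Th0, TSLP and Th2 cells (lines). At 72 h Il13 reached 327 CPM with TSLP against 81 in Th2 and 22.1 in Th0 cells, while Gata3 reached 387, 436 and 107 CPM.

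Counted time by time, 32, 33, 30, 161 and 251 genes were at least 2-fold apart between the TSLP and Th0 libraries at 2, 6, 24, 48 and 72 h. At 2 h 30 of the 32 were higher with TSLP, and at 72 h 94 were higher and 157 lower. With all libraries thinned to 21830854 reads the counts were 34, 36, 35, 167 and 249. For Th2 against Th0 the counts were 234, 82, 107, 243 and 341, and for TSLP against Th2 they were 125, 33, 93, 77 and 52. Markers of other cells at 72 h included Cst3 at 240 CPM in Th0, 75.6 in TSLP and 76 in Th2 cells, Cd74 at 166, 133 and 116 CPM, and Nkg7 at 14.2, 2.23 and 3.44 CPM. T cells express these 3 genes to some degree as well.

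**Figure D2:**
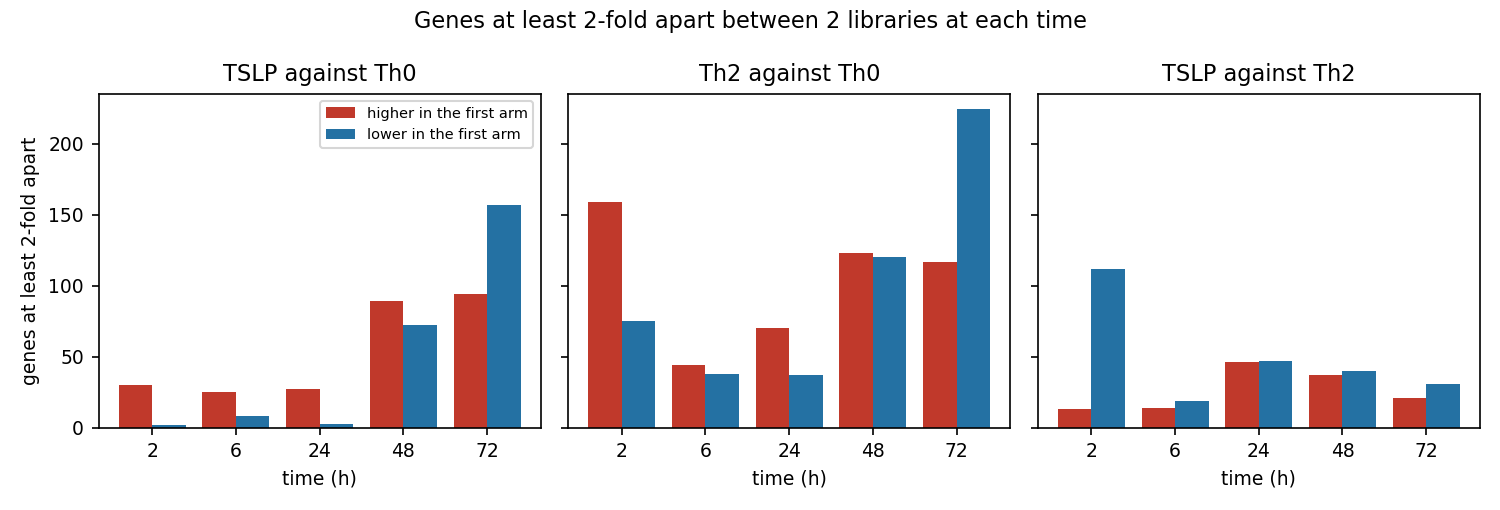
Number of genes at least 2-fold higher (red) or lower (blue) in the arm named in each panel at each time, with 1 library per arm and time. TSLP against Th0 went from 30 higher and 2 lower at 2 h to 94 higher and 157 lower at 72 h.

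IL-4 changed a broader set of genes than TSLP and raised Gata3 throughout. Gata3 was 1.79 log2 units higher in Th2 than in Th0 cells (SE 0.235, adjusted p 0.00449, 5 of 5 times). Among calls with a mean of at least 5 CPM and the same sign at all 5 times, the largest rise was in the cytokine gene Csf1, 3.37 units (SE 0.532, adjusted p 0.00801), which stood at 5.04 CPM in Th0, 8.13 in TSLP and 80.8 in Th2 cells at 48 h. The clock gene Npas2 rose by 2.83, Myo6 by 2.71, Inhba by 2.35, Pros1 by 2.17, Gpm6b by 2.00, Atf3 by 2.00 and Fgf2 by 1.99, with adjusted p from 0.00194 to 0.0433. Among the listed genes Ccr4 rose by 1.68 (SE 0.373, adjusted p 0.0311), Socs1 by 1.41 (SE 0.221, adjusted p 0.00801), Cd200r1 by 1.40, Nfil3 by 1.20, Ccr8 by 1.03 and Ccnd2 by 0.57. Id3 fell by 1.55 on the log2 scale (SE 0.246, adjusted p 0.00824), Wnt10b by 1.49, Nrn1 by 1.45, Tubb2b by 1.45, Zbtb32 by 1.38, Neurl3 by 1.32 and Bend4 by 1.25. The T cell surface receptor genes Cd5 and Cd6 fell by 0.74 (SE 0.0581, adjusted p 0.00015) and 0.55 (SE 0.0567, adjusted p 0.000469).

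The Th2 cytokine genes themselves did not pass in Th2 against Th0 cells. Il4 averaged 1.82 log2 units (SE 0.513, adjusted p 0.0727), Il13 1.20 (SE 0.393, adjusted p 0.115) and Il5 1.56 (SE 0.638, adjusted p 0.196). In the edgeR test of change with time, however, the Th2 effect on Il4 passed, with a slope of 0.65 per doubling (SE 0.137, adjusted p 0.043). So did that on Il21, with a slope of 0.69 (SE 0.143, adjusted p 0.0351) at a mean of 4.5 CPM. The slopes of Il13 and Il5 did not pass (adjusted p 0.304 and 0.19). Cish averaged 1.28 (SE 0.329, adjusted p 0.0521), with a read ratio of 5.83 at 2 h. Its slope of −0.46 passed (SE 0.0824, adjusted p 0.0298). Bcl6 averaged −0.41 (adjusted p 0.671), with a ratio of 0.138 at 2 h and 3.13 at 72 h (2.56 to 3.87), and its estimate was 0.22 with 2 h left out. Il1rl1 averaged 0.71 (adjusted p 0.0649), Il4ra 0.54 (0.16), Tbx21 0.69 (0.158), Ifng −0.06 (0.92), Foxp3 −0.42 (0.618), Crlf2 −0.08 (0.695) and Il7r 0.32 (0.638). Ifng was 0.11 with 48 h left out and 0.07 with 72 h left out. For Foxp3 the slope of the Th2 effect passed, at −0.72 (SE 0.117, adjusted p 0.0132), with a mean of 4.46 CPM. Each of these slopes rests on 1 library per arm and time.

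In Th2 against Th0 cells 618 genes passed, 235 higher and 383 lower, with 2430 at an unadjusted p under 0.05, and 124 of the 618 changed more than 2-fold. The count was 302 without 6 h, 218 without 24 h, 319 without 48 h, 331 without 72 h and 499 without 2 h. Of the 23 called genes named by rule, 13 kept their call whichever time was left out, among them Npas2, Myo6, Inhba, Pros1, Fgf2, Id3, Tubb2b, Zbtb32, Neurl3, Gata3, Nfil3 and Socs1. Csf1 lost its call only without 72 h (adjusted p 0.0574) and Bend4 only without 6 h (0.0705). Gpm6b lost its call whichever time was left out (adjusted p 0.056 to 0.154), Wnt10b with any but 6 h left out (0.105 to 0.131), Nrn1 with any but 72 h (0.0689 to 0.0947) and Ccr8 with any but 24 h (0.0686 to 0.139). Atf3 lost it without 2, 6 or 24 h (highest 0.0907), Ccnd2 without 2, 6, 48 or 72 h (0.108), Ccr4 without 6, 24 or 72 h (0.123) and Cd200r1 without 2, 48 or 72 h (0.0751). DESeq2 called 1144 genes, edgeR on only the libraries of these arms 195, the late libraries alone (24, 48 and 72 h) 387, and edgeR without the time block 0 (114 at unadjusted p under 0.05).

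Of the 26 genes called with TSLP, 25 had the same sign in Th2 cells and 21 were also called there, 11 higher and 10 lower. Independent lists of those sizes would share 0.319 and 0.325 genes, but the comparisons share their Th0 libraries. With arms simulated as unchanged against the same Th0 libraries, at most 1 call was shared in 20 draws. The TSLP calls not called in Th2 were Il13, Il5, Il9, Lama5 and Gpr83. Across all 11797 genes, which are not independent replicates, the TSLP and Th2 fold changes had r 0.741 and rho 0.676. Unchanged simulated arms gave a mean r of 0.483 and a mean rho of 0.446. The observed covariance was 0.0667, against a simulated mean of 0.0155 and a highest simulated value of 0.0173. With different Th0 libraries for the TSLP and Th2 arms, r was 0.476, rho 0.257 and the covariance 0.0578, and with the libraries exchanged 0.414, 0.263 and 0.0541. The share of genes with the same sign was 77.1%, against 67% for unchanged simulated arms (mean of the draws), and 57.5 and 57.3% with different Th0 libraries.

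Compared directly, TSLP cells had more Gpr83, Cd5 and Cd6 RNA than Th2 cells and less Lax1. Gpr83 was 0.77 log2 units higher in TSLP than in Th2 cells (SE 0.0973, adjusted p 0.018) and differed from Th0 by only −0.07 in Th2 cells. Cd5 was higher by 0.51 (SE 0.058, adjusted p 0.0112), Ahnak by 0.68 (SE 0.0952, adjusted p 0.0227), D8Ertd82e by 0.49, Gramd1a by 0.41 and Cd6 by 0.37 (SE 0.0566, adjusted p 0.0363). Lax1 fell by 0.62 on the log2 scale (SE 0.0878, adjusted p 0.0227), and the 8th call, Actn2, averaged under 5 CPM. The cytokine genes leaned towards TSLP without passing: Il13 was 1.69 units higher (SE 0.352, adjusted p 0.151), Il5 2.1 (SE 0.493, adjusted p 0.259) and Il9 2.08 (SE 0.429, adjusted p 0.148). At 72 h the ratio of TSLP to Th2 reads was 4.03 for Il13 (3.84 to 4.24) and 6.48 for Il5 (5.81 to 7.25). Il4 differed by 0.21 (adjusted p 0.966), Gata3 by −0.72 (0.465), Csf1 by −3.09 (0.0992), Bcl6 by −1.13 (0.658), Cish by −0.32 (0.917) and Ifng by 0.69 (0.565). Il4ra was −0.17 (0.936), Il1rl1 −0.26 (0.878), Tbx21 −0.20 (0.942), Foxp3 0.31 (0.942), Crlf2 −0.08 (0.942) and Il7r 0.07 (0.986). Il4ra was 0.11 and Tbx21 0.21 with 2 h left out, Crlf2 was 0.00184 with 48 h left out, and Il7r was −0.08 with 6 h left out.

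These 8 genes, 6 higher and 2 lower, were all that passed between TSLP and Th2 cells, with 866 at an unadjusted p under 0.05. The count was 0 without 6 h (676 unadjusted), 0 without 24 h (584 unadjusted), 3 without 48 h, 7 without 2 h and 10 without 72 h. Without 24 h the adjusted p was 0.206 for Gpr83 and Cd5, 0.351 for Cd6 and 0.329 for Lax1. DESeq2 called 93 genes and limma 5. edgeR called 15 on only the libraries of these arms, 2 with the late libraries alone and 0 without the time block (15 at unadjusted p under 0.05).

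The TSLP effect passed as changing with time in 4 genes, all of which went from higher early to lower late. Steeper slopes in both directions did not pass, among them Il5 at 0.91 (adjusted p 0.135), Akr1c18 at 0.76 (0.156) and Amica1 at −0.43 (0.135). Mdfic lost 0.34 log2 units per doubling of time (slope −0.34, SE 0.0385, adjusted p 0.00932), with 12 CPM in Th0 and 31 in TSLP cells at 2 h and 253 and 171 at 72 h. Selplg, which encodes the selectin ligand PSGL-1, had a slope of −0.25 (SE 0.0339, adjusted p 0.0251), Plscr1 −0.32 (0.0416, 0.0201) and Pkp4 −0.24 (0.0273, 0.00932). All 4 calls were lost without 2 h (adjusted p 0.245 for Mdfic, 0.103 for Plscr1, 0.144 for Selplg and 0.103 for Pkp4) and without 72 h (0.0948, 0.274, 0.274 and 0.0948). Only Mdfic was kept without 48 h. At an unadjusted p under 0.05 there were 929 genes, and the count was 2 without 2 h, 22 without 24 h, 1 without 48 h and 0 without 72 h (602 unadjusted), while DESeq2 called 123.

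Relative to Th0, Th2 cells had more Iigp1 and Tgtp1 RNA early than late and more Id2 and Epas1 RNA late than early. The slope of the Th2 effect was −0.79 for Iigp1 (SE 0.125, adjusted p 0.0154), which stood at 8.19 CPM in Th0 and 54.1 in Th2 cells at 2 h, and −0.64 for Tgtp1 (SE 0.126, adjusted p 0.041), at 16.5 and 125 CPM. Tgtp1 has a near-identical neighbour, so which gene its reads came from is uncertain. Gbp5 had a slope of −0.78, Rragd −0.77 and Amica1 −0.62 (SE 0.0783, adjusted p 0.00469). Id2 had a slope of 0.75 (SE 0.141, adjusted p 0.0342), with 30.6 CPM in Th0 and 417 in Th2 cells at 72 h. Epas1 had a slope of 0.94 (SE 0.167, adjusted p 0.0303), Rnd3 0.90, Akr1c18 0.77 and Gpm6b 0.70.

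In total 261 genes had a Th2 effect that changed with time, 94 rising and 167 falling. The count was 30 without 2 h and 76 without 72 h, and DESeq2 called 696. Of the 10 named genes, 1 kept its call without 2 h (Akr1c18), 6 without 6 h, 9 without 24 h, 2 without 48 h (Rnd3 and Amica1) and 3 without 72 h (Iigp1, Rragd and Amica1). The highest adjusted p was 0.351, for Tgtp1 without 2 h. With no filter on expression 7 of the 10 lost their call, all but Rnd3, Iigp1 and Amica1.

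Among lists of genes, the Th2 cytokines and the IL-4 response list were higher with TSLP than in Th0 cells. The Th2 cytokine list had a median of 1.18 log2 units over 11 genes (camera adjusted p 1.62e-17). It was 0.0182 with an estimated correlation. Of its members 3 were called and 9 adjusted over the list alone. The IL-4 response list had a median of 0.32 over 14 genes (adjusted p 6.93e-06, and 0.0182 with an estimated correlation), with 0 genes called and 4 adjusted over the list alone. Its largest changes were in Il24 (2.97, at a mean of only 0.81 CPM), Gata3 (1.07) and Nfil3 (0.57). The STAT5 feedback list had a median of 0.45 (adjusted p 4.82e-08), which became an adjusted p = 0.138 with an estimated correlation. It had 0 calls, with 7 higher and 1 lower adjusted over the list alone, led by Socs2 (1.18), Cish (0.96) and Socs1 (0.87) upward and Bcl6 (−1.54) downward.

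The CD4 T cell identity list had a median of −0.15 with TSLP (adjusted p 1.27e-05), which was adjusted p = 0.138 with an estimated correlation, with 0 calls and 3 lower adjusted over the list alone. The Th17 list had a median of −1.23 (adjusted p 0.00175), which was adjusted p = 0.258 with an estimated correlation. Its largest changes were in Ccr6 (−1.95) and Rora (−1.24), and 3 of its 5 genes were lower adjusted over the list alone. Cholesterol synthesis had a median of −0.12 (adjusted p 0.0207, and adjusted p = 0.672 with an estimated correlation), with Hmgcs1 (−0.26) the largest and 0 genes adjusted over the list alone. Th2 effector genes had a median of 0.17 (adjusted p 0.0278, and adjusted p = 0.157 with an estimated correlation), with 1 gene adjusted over the list alone. The list was led by Pparg (1.73, at a mean of only 2.13 CPM) and Cd200r1 (1.38).

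The other lists did not pass with TSLP. The camera adjusted p was 0.163 for Th1 genes (Il12rb2 0.82, Eomes −0.71), 0.379 for follicular helper genes (Il21 1.44, Pou2af1 −1.15), 0.274 for regulatory T cell genes (Il2ra 0.63, Ikzf2 −0.53), 0.865 for cytokine receptors (Il2ra 0.63, Il7r 0.39), 0.128 for immediate early genes (Nr4a2 −0.50, Dusp1 −0.47) and 0.549 for quiescence genes (Ccr7 −0.66, Bach2 −0.34). It was 0.125 for cell cycle (Rrm2 0.25, Ccne2 0.23), 0.128 for glycolysis (Hk2 0.24, Pgk1 0.21), 0.136 for ATF4 genes (Vldlr −0.23, Asns 0.16), 0.837 for interferon-stimulated genes (Socs1 0.87, Gbp3 −0.59), 0.531 for survival genes (Bcl2 0.72, Bcl2l11 −0.52) and 0.837 for checkpoint receptors (Havcr2 0.97, Cd160 −0.83). Among the marker lists it was 0.622 for B, 0.837 for CD8 T, 0.245 for NK, 0.531 for myeloid and dendritic, and 0.977 for basophil and mast cells, and none of the 7 erythroid genes was measured. The test's direction was up while the median was negative for regulatory T cell genes, cytokine receptors, interferon-stimulated genes and basophil markers, and down while the median was positive for CD8 T cell markers. The mean was positive for regulatory T cell genes and cytokine receptors and negative for interferon-stimulated genes. With 72 h left out 12 lists passed in place of 7.

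With IL-4, 7 lists passed against Th0. CD4 T cell identity had a median of −0.26 (adjusted p 4.08e-08, and adjusted p = 0.0692 with an estimated correlation), with Cd5, Cd4 (−0.39) and Zap70 (−0.30) called and 8 genes lower adjusted over the list alone. The IL-4 response list had a median of 0.28 (adjusted p 8.8e-06) and was the only list that also passed with an estimated correlation, at 0.0182, with 2 genes called and 7 adjusted over the list alone. Th17 genes had a median of −1.33 (adjusted p 0.000375, and adjusted p = 0.356 with an estimated correlation), led by Ccr6 (−2.76). Th2 cytokines had a median of 1.20 (adjusted p 0.000564, and adjusted p = 0.403 with an estimated correlation), with 0 called and 6 adjusted over the list alone. The feedback list had a median of 0.20 (adjusted p 0.00692, and adjusted p = 0.464 with an estimated correlation), cell cycle 0.10 (0.00692, and adjusted p = 0.409 with an estimated correlation) and cholesterol synthesis −0.15 (0.0146, and adjusted p = 0.696 with an estimated correlation). The other lists had adjusted p from 0.108 for interferon-stimulated genes to 0.973 for basophil markers. Within them Satb1 rose by 0.85 (adjusted p 0.00236) and Havcr2 by 1.73 (0.00711), and Cxcr3 fell by 0.98 (0.0208), Dusp1 by 0.68 (0.00801) and Bbc3 by 0.69 (0.0153). For Th1, glycolysis and ATF4 genes the test's direction was up while the mean was −0.05, −0.00446 and −0.02, and the median was positive for the latter pair.

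Between TSLP and Th2 cells, Th2 cytokines were higher with TSLP (median 0.23, adjusted p 0.000246), as were CD4 T cell identity genes (0.07, 0.00194) and regulatory T cell genes (0.24, 0.0034), and interferon-stimulated genes were lower (−0.23, 0.0275). None held with an estimated correlation, where the first 3 had adjusted p = 0.272 and the last adjusted p = 0.593 with an estimated correlation. Adjusted over the list alone, 4 cytokine and 2 identity genes passed. The remaining 20 lists had adjusted p of at least 0.0698. With 2 h left out 7 lists passed, and with 72 h left out 10 did. The test's direction differed in sign from the median for Th2 effector genes, NK markers and survival genes, and from the mean for Th2 effector genes, follicular helper genes, NK markers and B cell markers.

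**Figure D3:**
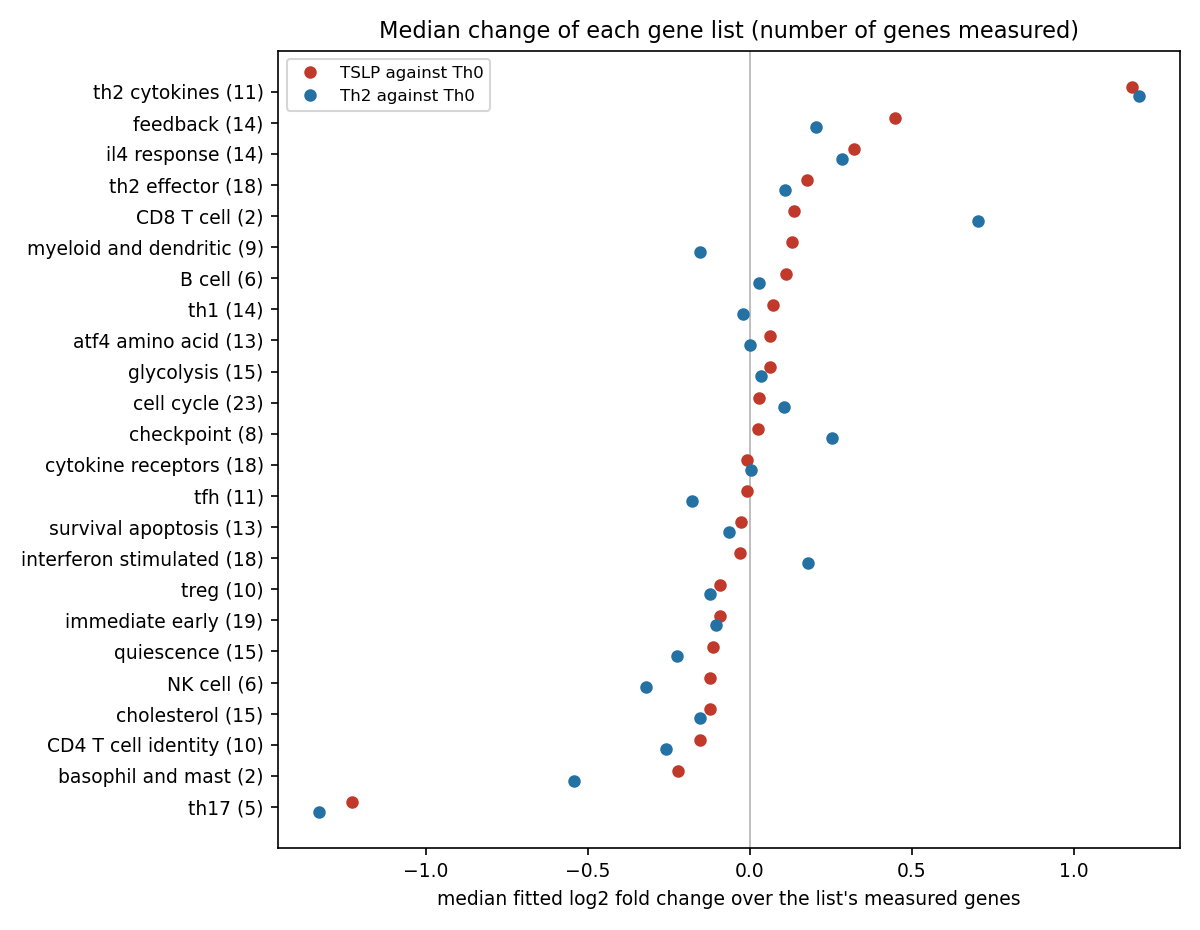
Median fitted log2 fold change against Th0 of each list of genes (number of measured members in brackets) in TSLP (red) and Th2 (blue) cells, fitted over 5 times. Among the TSLP medians, Th2 cytokines were highest at 1.18 and Th17 genes lowest at −1.23. In Th2 cells the same lists stood at 1.20 and −1.33.

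Th0 cells differed from the naive library in far more genes than either cytokine arm differed from Th0. No culture without stimulation was sampled, so activation cannot be told apart from culture itself. Against the naive library, 2157, 2901, 3878, 4414 and 3730 genes were at least 2-fold apart in Th0 cells at 2, 6, 24, 48 and 72 h. At 2 h 955 were higher and 1202 lower, a split that became 623 and 1603 when libraries were scaled by their totals alone. At 2 h Sema7a went from 3.14 to 574 CPM, Nr4a3 from 50.2 to 2420, Egr2 from 19.8 to 836, Nr4a2 from 40.5 to 1540 and Zfp948 from 1.77 to 131. Dtx1 went from 282 to 8.56 CPM, Jun from 705 to 48, Tet1 from 71.8 to 2.7, Slc16a5 from 42.8 to 2.05 and Rmnd1 from 27.6 to 0.43. At 72 h Il2ra stood at 1810 CPM against 6.44 in naive cells, Tg at 356 against 0.157, the asparagine synthetase gene Asns at 413 against 0.55, Wisp1 at 208 against 0.118 and Cth at 271 against 0. The quiescence and exit genes Klf2 and S1pr1 went from 847 to 3.07 and from 1530 to 8.87 CPM, Pydc3 from 263 to 0.0853, Fosb from 336 to 1.24 and Dtx1 to 0.938.

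Many lists also shifted between the naive library and the Th0 time course. Of 19 immediate early genes 13 were at least 2-fold higher at 2 h (median 2.49 log2 units, at percentile 100 of 10000 matched random lists), and 4 were at least 2-fold lower: Jun (705 to 48 CPM), Junb (1550 to 437), Fosb (336 to 106) and Dusp1 (305 to 93.5). All 23 cell cycle genes were at least 2-fold higher at 24 h (median 3.93) and at 48 h (4.43), and 20 at 72 h (3.32). All 13 ATF4 and amino acid genes were higher at 72 h (3.86), 12 of 15 glycolysis genes (2.31) and 13 of 15 cholesterol genes (2.51) at 48 h. Quiescence genes were lower at 24 h in 12 of 15 cases (median −2.23). By 72 h 16 of 18 interferon-stimulated genes (−2.90), 5 of 6 NK markers (−2.53) and 6 of 9 myeloid markers (−2.57) were at least 2-fold lower than in naive cells, Lyz2 going from 103 CPM to 0 reads, while the myeloid marker Cst3 was higher.

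TSLP peaks were found more often among Th2 than among Th0 peaks for all 3 marks. For H3K27Ac, a mark of active promoters and enhancers, the lists held 30557 peaks in Th0, 29242 in TSLP and 29593 in Th2 cells. Of the TSLP peaks 80.73% were overlapped by Th2 peaks and 69.97% by Th0 peaks (Wilson 95% interval 69.45 to 70.5). For H3K4Me3, a promoter mark, there were 21480, 20089 and 20848 peaks, and 94.11% of the TSLP peaks were overlapped in Th2 and 91.26% in Th0. In the other direction Th2 H3K4Me3 peaks were overlapped slightly more often in Th0 (85.87%) than in TSLP cells (84.22%). For H3K36Me3, which covers transcribed gene bodies, there were 127359, 124025 and 149216 peaks, and the shares were 78.6 and 67.48%. The Th2 lists covered more bases than the Th0 lists, 25.91 against 21.85 Mb for H3K27Ac, 23.57 against 22.46 for H3K4Me3 and 75.97 against 57.61 for H3K36Me3, which by itself favours overlap with Th2. Strong H3K27Ac peaks numbered 10325 in Th0, 15018 in TSLP and 13616 in Th2 cells. Those absent from the other list numbered 963 in TSLP against Th0 (6.41%) and 107 the other way (1.04%). They were 743 in Th2 against Th0 (5.46%) and 164 the other way (1.59%), and 161 in TSLP against Th2 (1.07%) and 75 the other way (0.55%). The median fold enrichment of the H3K27Ac lists was 5.84 in Th0, 7.56 in TSLP and 6.84 in Th2 cells. Their median pileup was 8, 14 and 11 in the same order. More strong peaks in the cytokine arms therefore cannot be told apart from a difference in signal between whole libraries.

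At the Th2 cytokine locus, more H3K27Ac peaks were called at Il4 and Il13 in both cytokine arms than in Th0. The Th0 H3K27Ac list had the lowest median pileup, 8 against 14 in TSLP and 11 in Th2 cells. Larger counts or lengths in the cytokine arms may thus reflect whole libraries as well as single loci. Peaks were counted by the gene the authors annotated, so they can lie outside the gene coordinates given here. Peaks annotated to Il13 (chromosome 11, 53631323 to 53634702, GRCm38) numbered 0 in Th0, 5 in TSLP and 3 in Th2 cells, covering 0, 4335 and 561 bp. At Il4 (53612461 to 53618665) there were 1, 6 and 6 peaks covering 231, 9719 and 8695 bp, and at Il5 (53720794 to 53725103) 0, 1 and 0. Rad50, which carries the locus control region in its introns, had 7, 6 and 4 peaks, covering 5938, 15147 and 11840 bp. H3K4Me3 peaks numbered 0, 2 and 3 at Il4, 0, 1 and 0 at Il13 and 0 in each arm at Il5. Gata3 (chromosome 2, 9857078 to 9878600) had 13 H3K27Ac peaks in Th0, 34 in TSLP and 34 in Th2 cells, covering 10535, 37012 and 39412 bp, and its H3K36Me3 peaks numbered 15, 29 and 51. H3K27Ac peaks numbered 6, 4 and 2 at Bcl6 (7059, 7874 and 7349 bp, highest fold 27.26, 42.82 and 53.02) and 1 in each arm at Cish (15978, 21795 and 21696 bp, fold 31.16, 67.51 and 72.41). Fold enrichment was scored within each list, so these folds do not compare the amount of the mark between arms. There were 7, 9 and 10 at Tbx21 (2385, 6246 and 6745 bp), 2, 1 and 1 at Il1rl1 (531, 169 and 155 bp), and 0 at Ifng and Foxp3.

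**Figure D4:**
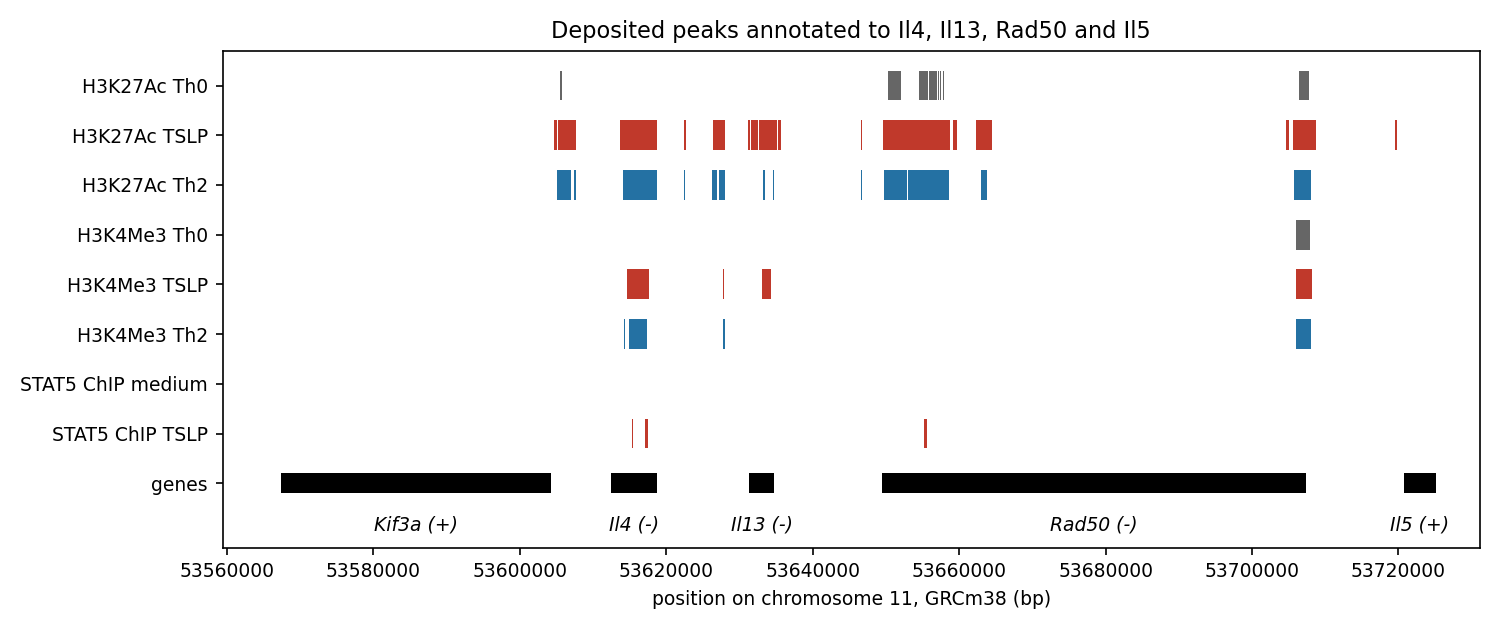
Peaks of H3K27Ac and H3K4Me3 at 72 h and of STAT5 across the Il4, Il13, Rad50 and Il5 region of chromosome 11 (GRCm38 position in bp), each bar a peak from 1 library. H3K27Ac peaks annotated to Il13 numbered 0 in Th0, 5 in TSLP and 3 in Th2 cells.

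For H3K27Ac and H3K4Me3, genes with a peak in a cytokine arm and none in Th0 had slightly higher RNA in that arm at the preset correlation between genes, and none of these sets passed with an estimated correlation. The 512 measured genes with an H3K27Ac peak in TSLP but not Th0 cells had a median log2 ratio of 0.07 at 72 h, at percentile 100 of 10000 matched random lists, whose medians lay between −0.05 and −0.0016 in their central 95%. In camera over the 5 times they had adjusted p 0.00366, which was adjusted p = 0.144 with an estimated correlation, and 41 were at least 2-fold higher at 72 h and 2 lower. The 340 genes with a peak in Th0 but not TSLP cells had a median of −0.17 (adjusted p 0.00171, and adjusted p = 0.155 with an estimated correlation). For Th2 against Th0 the medians were 0.04 for 562 genes (adjusted p 0.00732, and adjusted p = 0.15 with an estimated correlation) and −0.23 for 328 genes (0.000471, and adjusted p = 0.144 with an estimated correlation). H3K4Me3 gave 0.12 for the 92 genes of TSLP (adjusted p 0.000364) and −0.17 for the 156 genes absent from Th2 (0.000317), both with adjusted p = 0.144 with an estimated correlation. H3K36Me3 gave 0.05 for 360 genes of TSLP (adjusted p 0.0678, and adjusted p = 0.242 with an estimated correlation) and −0.27 for 378 genes absent from Th2 (1.68e-05, and adjusted p = 0.144 with an estimated correlation).

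After brief TSLP treatment STAT5 peaks were called at many sites, among them nearly all genes of the feedback list. The list from cells in medium held 582 peaks and that from TSLP-treated cells 6908. In medium 4.5% of the peaks lay in promoters and 42.4% between genes, and with TSLP 23.2 and 22.7%, with a further 36.9% in introns. TSLP peaks overlapped 47.59% of medium peaks (95% interval 43.57 to 51.65), and medium peaks overlapped 4.13% of TSLP peaks (3.68 to 4.62). With TSLP, 13 of the 14 feedback genes carried a peak, all but Socs2, as did 10 of 14 IL-4 response genes, 15 of 19 immediate early genes, 13 of 15 quiescence genes, 4 of 12 Th2 cytokine genes and 5 of 23 cell cycle genes. Among all 11797 genes tested for RNA, 23.3% carried a TSLP peak. In medium 0 genes of any list carried one, but that list was annotated to only 219 genes, against 3726 with TSLP. Gata3 carried 15 peaks with TSLP (highest fold enrichment 15.07), Il1rl1 3, Il4 and Cish 2 each, Bcl6, Ifng and Rad50 1 each, and Il13, Il5, Tbx21 and Foxp3 0.

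The 10 TSLP peaks of highest fold enrichment, from 161.33 to 334.38, were all overlapped by medium peaks and by peaks in all 9 histone lists. The highest lay between genes on chromosome 2 at 98662159 to 98663054. Others lay near Cdon on chromosome 9 (35305135 to 35305669, fold 310.38) and in an intron of Chl1 on chromosome 6. Among the peaks with no overlapping medium peak, the highest was at the promoter of Lta (chromosome 17, 35205047 to 35205841, fold 42.98). Promoter peaks of Cish (chromosome 9, 107295323 to 107297169, fold 35.17) and Bcl6 (chromosome 16, 23988058 to 23989153, fold 32.38) and an intron peak of Bcl2 (chromosome 1, 106600590 to 106601416, fold 32.94) were among the next 9. Of the TSLP peaks 56.3% overlapped H3K27Ac peaks of TSLP cells, 55.44% those of Th2 cells and 52.1% those of Th0 cells. These H3K27Ac lists covered 26.08, 25.91 and 21.85 Mb, which by itself favours overlap with the TSLP and Th2 lists.

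Genes with a STAT5 peak made up 6 of the 16 higher and 4 of the 10 lower TSLP calls, against 2750 of the 11797 genes tested (23.3%). They included Il9, Inhba, Kcnk5, Nek6, Gpr146 and Inpp4b among the higher and Itm2a, Traf1 and Lrig1 among the lower. In Th2 cells 109 of the 235 higher (46.4%) and 135 of the 383 lower calls (35.2%) carried one. As a set the 2750 genes did not shift with TSLP in camera (p 0.531, and 0.605 with an estimated correlation), and their median at 72 h was −0.01. The genes of the 500 peaks of highest fold gave p 0.000486 upward (0.186 with an estimated correlation), although their median at 72 h was −0.04. Their median fitted over the 5 times was 0.05, at percentile 100 of the matched random lists. Ranking by fold favours peaks that medium peaks overlap, whose median fold was 10.05 against 5.58 for the others. The p was 0.268 for genes with a promoter peak and 0.569 for those of peaks with no medium overlap.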

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

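The tests of cells of another type in the 72 h Th0 library, of the shared Th0 libraries and all comparisons with other splits of the libraries were chosen after the results were seen. The resampling of genes behind the test of IL-4 was also added after. The tests of library size, of regions that give peaks whatever the antibody and of IL-4 made in the TSLP cultures were written before.

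The effects of the cytokines differed between times in some genes, by a test of arm against log2(hours). The TSLP effect passed this test in 4 genes, with slopes per doubling of time of −0.34 for Mdfic, −0.32 for Plscr1, −0.25 for Selplg and −0.24 for Pkp4. Among 100 splits of the 10 TSLP and Th0 libraries, 6 gave at least as many genes and the highest of the others gave 74, so chance is not excluded for the count of 4. Some splits exchange the arms between early and late times, and a steady TSLP effect then appears as a slope. Such splits are not free of the TSLP effect, so the count of 74 is no clean measure of chance. Its cause was not tested. The calls were lost without 2 h, where the adjusted p was 0.245 for Mdfic, 0.103 for Plscr1, 0.144 for Selplg and 0.103 for Pkp4.

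The Th2 effect changed with time in 261 genes. The slopes were 0.94 for Epas1, 0.90 for Rnd3, 0.77 for Akr1c18, 0.75 for Id2, 0.70 for Gpm6b, −0.79 for Iigp1, −0.78 for Gbp5, −0.77 for Rragd, −0.64 for Tgtp1 and −0.62 for Amica1. Of 100 splits 2 reached 261, and the highest of the others gave 727 genes. The real split and that one both kept 1 library of each time in each group, and the 13 drawn splits that did so are too few for a share under 0.05. The split with 727 genes grouped Th0 libraries of early times with Th2 libraries of late times, and the reverse. A steady Th2 effect appears as a slope in such a split. The count of 727 therefore carries the Th2 effect and is no measure of chance. For this reason too, the splits cannot tell whether the count of 261 came by chance. Without 2 h the count was 30 and without 72 h it was 76.

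Peaks on the mitochondrial chromosome were outside the comparisons and were more numerous in some cytokine lists than in Th0. H3K4Me3 gave 17 in Th2 and 14 in TSLP cells against 5 in Th0, and H3K27Ac gave 6 in Th2 cells against 4 in Th0. No cause was tested for them.

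More genes were 2-fold apart between TSLP and Th0 cells at 48 and 72 h than before. Library size is argued against: thinned to the smallest total, the libraries gave 249 genes at 72 h and at most 36 at 2, 6 and 24 h. Cells of another type in the 72 h Th0 library would leave 48 h as it was, yet 161 genes were apart there against at most 33 earlier. For 72 h, 40% of the 5 measured markers of other cells were at least 2-fold lower with TSLP, namely Cst3 (240 against 75.6 CPM) and Nkg7 (14.2 against 2.23 CPM), which T cells also express. Against such cells, 58.3% of the 12 markers seen in the naive library were below 1 CPM in Th0 cells at 72 h, Lyz2 among them at 0. Cst3 and Cd74 went the other way, from 22.5 and 9.23 CPM in naive cells to 240 and 166 in Th0 cells at 72 h, so cells of another type stay open for that time. The counts of Th2 against Th0 rose as well, from 82 and 107 at 6 and 24 h to 243 and 341 at 48 and 72 h, after 234 at 2 h. Those of TSLP against Th2 went from 93 at 24 h to 77 and 52. Late Th0 libraries that deviated as a whole therefore stay open too. A later action of TSLP may explain the rise at 48 h, as a hypothesis found and tested on the same data that these counts cannot single out.

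The 10 STAT5 peaks of highest fold enrichment after TSLP were also in the medium list. The test was how many of them peaks in all 9 histone lists overlapped, and the value was 10. This is consistent with regions that give peaks whatever the antibody, and no biological explanation was tested for them. The highest peaks that no medium peak overlapped, at Lta, Cish, Bcl2 and Bcl6 among others, were in 2 to 6 of the 9 histone lists.

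TSLP and Th2 moved many of the same genes the same way, although the comparisons share their Th0 libraries. Sharing them gave a covariance of at most 0.0173 in 100 simulated draws, against 0.0667 observed. The draws held the spread of single genes only, so they cannot speak to a Th0 library that deviated as a whole. With different Th0 libraries, and so different times, for the arms the covariance was 0.0578 and 0.0541. As no library was shared there, these values argue against sharing as the whole cause. The share of genes with the same sign was 57.5 and 57.3% in these fits. With the Th0 libraries shared it was 77.1%, against 67% on average and at most 68% in the simulated draws. IL-4 made in the TSLP cultures would give a response that grows later. For 233 genes that stood 2-fold apart between Th2 and Th0 cells at 2 h, the TSLP median was 85.9% of the Th2 median at 6 h, 74.8% at 24 h, 162% at 48 h and 76.1% at 72 h, and 29.2% at 2 h, where they were chosen. Resampling the genes gave 66.3 to 116% at 6 h, 56.5 to 113% at 24 h, 105 to 253% at 48 h and −389 to 422% at 72 h, where the Th2 median itself was only 0.04. The 48 h share goes the way that IL-4 predicts, but its range overlaps that of 6 h, and the TSLP median fell from 0.25 to 0.16 between these times. So IL-4 made in the cultures and a shared direct action of both cytokines cannot be told apart. A direct action of TSLP through STAT5 stays among the explanations that these libraries leave open.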

How the results depend on the processing

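The fits with only the 24, 48 and 72 h libraries and the STAT5 set without medium peaks were chosen after the data were seen; the other alternatives were planned. RLE size factors, no filter and a filter of 5 CPM in 3 libraries kept every count of genes within 1.5 times, but with no filter 7 of the 14 named genes with a changing effect lost their call (Epas1, Akr1c18, Id2, Gpm6b, Gbp5, Rragd and Tgtp1, all in Th2 cells). For the named genes in comparisons of arms, DESeq2 left 78 of 84 on the same side of the threshold and moved 6 past it, RLE left 82, and limma on log2(RPKM + 1) left 64. With 1 time left out, 289 of 420 values were the same, 122 lost their call and 9 reversed.

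For TSLP against Th0, 26 genes became 208 with DESeq2, 7 with limma on log2(RPKM + 1), 15 with log2(RPKM + 0.1) and 52 with only the libraries of these arms. Without the time block the count was 0 in edgeR (40 at unadjusted p under 0.05), because time then counts as spread. For Th2 against Th0, 618 became 1144 with DESeq2, 195 with the libraries of these arms, 0 without the block (114 unadjusted) and 387 with the late libraries alone. For TSLP against Th2, 8 became 93 with DESeq2, 5 with either limma fit, 15 with the libraries of these arms, 0 without the block (15 unadjusted) and 2 with the late libraries. For changes with time, the 4 TSLP genes became 39 with hours on a linear scale and 123 with DESeq2, and the 261 Th2 genes 696 with DESeq2. Of the named genes called in the main fit, 29 kept their call under limma on log2(RPKM + 1). Apart from the time block, the cause was not tested. Fitting only the libraries of the compared arms raised 2 of the counts and lowered the other.

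With each time left out, the counts ranged from 0 to 48 for TSLP against Th0, 218 to 499 for Th2 against Th0 and 0 to 10 for TSLP against Th2. They ranged from 0 to 22 for changes of the TSLP effect and 30 to 296 for the Th2 effect. Named genes that kept their call ranged from 19 to 35, and lists that passed from 6 to 12, 5 to 10 and 3 to 10 in the 3 comparisons. Values that reversed belonged to genes without a call. In log2 units, Foxp3 in TSLP against Th0 ranged from −0.32 to 0.077 (0.077 without 24 h and 0.0098 without 48 h). Bcl6 in Th2 against Th0 ranged from −0.83 to 0.22 (0.22 without 2 h), and Ifng from −0.25 to 0.11 (0.11 without 48 h and 0.0745 without 72 h). In TSLP against Th2, Il4ra ranged from −0.301 to 0.11 and Tbx21 from −0.37 to 0.21 (both highest without 2 h), Crlf2 from −0.18 to 0.0018 (highest without 48 h) and Il7r from −0.0816 to 0.2012 (lowest without 6 h).

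With an estimated correlation, 2, 1 and 0 lists passed in TSLP against Th0, Th2 against Th0 and TSLP against Th2 in place of 7, 7 and 4, and with fry 3, 4 and 0. Camera's 18 calls held in 3 cases with the estimate, 6 with fry and 18 with RLE. The STAT5-bound genes went from p 0.531 to 0.000486 with the 500 peaks of highest fold (0.186 there with an estimated correlation), and were 0.268 to 0.605 under the other alternatives.

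Counts of genes 2-fold apart moved with the floor. For TSLP against Th0 a floor of 1 CPM gave 53 at 6 h and 58 at 24 h. A floor of 20 CPM gave 14 at 6 h, 15 at 24 h, 93 at 48 h and 138 at 72 h. For Th2 against Th0 a floor of 1 CPM gave 397 at 48 h, and a floor of 20 CPM gave 45, 67, 130 and 184 at 6, 24, 48 and 72 h. Fewer genes pass a higher floor by construction. A pseudocount of 0.1 and scaling by totals kept all 15 counts within 1.5 times. The correlation of TSLP and Th2 effects across genes was 0.778 for genes of at least 5 CPM and 0.476 and 0.414 with the Th0 libraries split by time, where rho fell from 0.676 to 0.257 and 0.263.

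Shares of overlapped peaks depended on the rule, in percent. With at least a share of 0.5 of the peak covered, H3K4Me3 gave 87.08 (TSLP in Th0), 77.93 (Th0 in TSLP), 80.09 (Th2 in Th0) and 82.84 (Th0 in Th2), and in the same order H3K27Ac gave 58.89, 72.2, 56.9 and 70.04 and H3K36Me3 50.56, 51.31, 39.96 and 62.48. With a −log10 q of at least 10 in both lists the shares were 92.31, 96.5, 89.21 and 97.79 for H3K4Me3, 63.72, 95.19, 67.08 and 92.83 for H3K27Ac, and 41.36, 60.14, 37.56 and 63.46 for H3K36Me3. With equal numbers of top peaks they were 89.86, 86.87 and 89.64 for H3K4Me3 (Th2 in Th0 did not move), 68.95, 80.14 and 78.22 for H3K27Ac (likewise), and 66.66, 67.88, 62.49 and 72.21 for H3K36Me3. By this rule TSLP peaks were still overlapped more often in Th2 than in Th0, at 93.38 for H3K4Me3, 80.42 for H3K27Ac and 73.66 for H3K36Me3, although equal numbers do not make the covered bases equal. The strict threshold gave 68 and 12.02 for STAT5 peaks of medium in TSLP and of TSLP in medium. The cause was not tested beyond the stricter rule itself.

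The planned search for the STAT5 motif was not run, because it needs genome sequence. Depth limits scarce genes most: Il4 rested on 9 reads in Th0 cells at 72 h.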

Other observations

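The comparisons with other splits of the libraries were chosen after the results were seen. Each used 100 splits of the 10 libraries of a pair of arms into groups of 5, the real split included.

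For TSLP against Th0 the real split called 26 genes and the highest of the others 15, with 1 split of 100 as large. For Th2 against Th0 the real split called 618 genes and the highest of the others 19, with 1 split as large. For TSLP against Th2 the real split called 8 genes and 2 splits of 100 were as large, the other of which gave 16, more than the real one. These shares are under 0.05, but most of the splits put unequal numbers of a time in the groups, unlike the real one. Of the 13 drawn splits that kept 1 library of each time in each group, the real one included, the others gave at most 0, 13 and 0 genes in the 3 comparisons, and 13 splits are too few for a share under 0.05.

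For the lists of genes chance is not excluded. Of the same 13 splits the others gave up to 9, 13 and 7 lists. With TSLP against Th0, 7 lists passed, and 23 of the 100 splits gave as many, the highest 13. With Th2 against Th0, 7 lists passed, and 26 splits gave as many, the highest 13. With TSLP against Th2, 4 lists passed, and 40 splits gave as many, the highest 11. For the genes with a peak in 1 arm, 5 sets passed for TSLP, and 25 splits gave as many, the highest 6. For Th2 6 sets passed, and 8 splits gave as many, the highest 6.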
